A study of Triticum aestivum with 16 samples.

How the data were processed

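Transcript levels were measured in flag leaves of 8 recombinant inbred wheat lines from a cross of Seri M82 and Babax, sampled 6 to 8 days after anthesis in an irrigated field in 2007. Each line had 2 field replicates, which gives 16 arrays of biotin-labelled total RNA on an Affymetrix wheat array. The labels call the replicates biological and name a field replicate number for each array. They give no water soluble carbohydrate level or class for any line, so lines were compared one against the others and in pairs, and no grouping into high and low lines was made.

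The deposited values are on a log2 scale. Per the submitters' processing notes, RMA and GCRMA were used, with no versions and no statement of which produced the table. These are methods that correct the background of an array, normalize arrays to each other and summarise the probes of a probe set into 1 value. The deposited log2 values have a floor at 2.25, where 37.71% of them lie, and they reach 16.67. Array medians lay between 2.35 and 2.39. Of 61290 probe sets, 175 controls were left out of the tests, and of the 61115 tested, 11747 were constant over the 16 arrays (range under 1e-06). Detection calls were not used here, and a value at the floor gives no order between lines. The number of arrays, 2 per line, limits the precision.

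Arrays of 1 line had equal values (tolerance 1e-09) for a median of 11.5% of probe sets above the floor, and arrays of different lines for a median of 11.2%, so no pair of arrays was treated as a repeat of the same hybridisation.

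The platform annotation pairs 1273 probe sets with 1 gene each, 771 genes in all, and none with several. 59842 probe sets have no gene in it and are unnamed here. Symbols were updated through gene identifiers to the RefSeq annotation of the IWGSC CS RefSeq v2.1 assembly, where 1272 of the 1273 were found. Only 102 genes have a name or synonym there, and the others carry a locus number. No coordinates are given, because no genome build is named for the array.

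Line effects were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes) as a moderated F over the 8 lines. Each line was also tested against the mean of the other 7 lines and in the 28 pairs, all in 1 fit with 8 residual degrees of freedom. P-values were adjusted by the Benjamini-Hochberg method, within each line contrast and over all probe sets and pairs together for the pairs, with a threshold of 0.05. The prior degrees of freedom came to 0.39, so the residual spread of a probe set was hardly moderated. The field replicates were compared with line as a block. The share of variance between lines was the one-way intraclass correlation.

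Before the data were examined, 35 gene lists were fixed as patterns to be found in symbols, synonyms or descriptions. The tests, the alternatives and the rule for naming genes were fixed with them. The search as run covered symbols and synonyms only. Of the 35 lists, 29 had no member by this search, among them fructan synthesis, invertase, sucrose synthesis, starch synthesis, Calvin cycle and light harvesting. Most genes carry only a locus number, so an empty list does not show that its genes were absent from the array. Genes of carbon fixation, starch, tubulins and histones were annotated and enter the further lists below. Only 2 lists had the 3 members required for a set test. Those were tested with camera (preset correlation 0.01), with an estimated correlation, with fry, and with a two-sided Fisher's exact test on the share of members with a line effect. A planned score for fructan synthesis had no members. 7 further lists were built from the symbols in the annotation after the results had been seen, with 1 probe set per gene.

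Genes were named by rule, 1 probe set per gene with the lowest p: the 20 annotated genes with the widest range of line means among those with a line effect; up to 3 higher and 3 lower genes per line with both replicates on the same side of the other lines; up to 4 members of each list; and every member of the fructan hydrolysis list. A few further genes are named after their values were seen, and this is said where they appear.

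The limma steps were tested on simulated data for the contrast of SB80 with the other lines over 61115 probe sets, with independent normal noise. Each size had 50 changed probe sets, all with a mean more than 2 above the floor, so recovery nearer the floor was not tested. Of these, 36% were found at a log2 difference of 0.5, 70% at 1, 98% at 2 and 100% at 3, with 12 false calls. The moderated F over the 8 lines found 3, 15, 36 and 45 of the 50 at these sizes, with 10 false calls. Alternatives covered filters on dim probe sets, quantile normalization, subtraction of array medians, another prior, array weights, a minimum difference, the field replicate as a block, and leaving out each array. The array weights came out equal for both arrays of every line, such as 0.743 for each array of SB80. They therefore weight lines by their replicate spread and cannot mark a single array as poor. Exact tests and tables used Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3.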

Results

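Flag leaf transcripts of 8 recombinant inbred lines of bread wheat were compared, each line with 2 field replicates. The lines descend from a cross of the cultivars Seri M82 and Babax, and the series concerns differences between genotypes in the metabolism of water soluble carbohydrates, which in wheat are mainly fructans and sucrose. Over the 30557 probe sets with the highest mean signal, arrays of the same line correlated at 0.9945 to 0.997, and arrays of different lines at 0.9792 to 0.992. The first principal component held 21.2% of the variance and the second 14.8%.

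The first comparison asked which transcripts differed between the lines. The fructan exohydrolase 6-FEH (LOC780575), an enzyme that breaks down fructan, differed between lines on 2 of its 3 probe sets. On the probe set with the wider range it was highest in SB80, at 8.04 ± 0.074 (log2, SD, n = 2), and lowest in SB15, at 4.77 ± 0.0087, a range of 3.27 (limma adjusted p = 0.0198). Its brighter probe set ranged over 1.69 between the same lines (limma adjusted p = 0.00273), and the third lay near the floor at a mean of 2.29. The call of the wider probe set ended without either array of SB15 or without SB80, while that of the brighter one held in every setting run. The other fructan exohydrolase with a probe set, 1-FEHw2 (LOC543441), had a mean of 12.42 and a range of 0.37, with a limma adjusted p of 0.597.

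The widest ranges among annotated genes belonged to genes that carry only a locus number. LOC543287 reached 9.74 ± 0.92 (SD, n = 2) in SB165 and lay between 2.69 and 5.03 in the other lines, a range of at least 7.05. In SB53, SB80, SB138 and SB189 it lay between 2.69 and 2.92, near the negative controls at 2.26, so these levels are upper bounds. LOC543313 ranged over 6.14, from 4.56 in SB80 to 10.7 in SB165. Both line effects ended when SB165 was left out. LOC780687 ranged over 4.33 and was highest in SB189 (7.77 ± 0.094) and SB80 (7.49 ± 0.069). LOC542773 ranged over 3.21, with 11.12 ± 0.67 in SB189, 10.91 ± 0.33 in SB80 and 7.91 ± 0.58 in SB165. It was also low in SB146 (8.2 ± 0.12) and SB15 (8.3 ± 0.23), and high in SB33 (10.37 ± 0.18). Its second probe set gave a range of 2.47 and a correlation of 0.97 with the first over line means. LOC542774 ranged over 2.19, also between SB189 and SB165, but its line effect ended in 10 of 16 runs that left out 1 array, with array weights and without SB80. LOC780602 was low in SB80 (5.27 ± 0.0084) and SB189 (6.17 ± 0.26) and lay between 8.27 and 8.83 in the other lines (limma adjusted p = 1.98e-06). Its 4 other probe sets had ranges of 0.45 to 0.55 and no line effect, so the difference rests on 1 probe set. For LOC606345 and LOC606369, a second probe set with a line effect ran the opposite way over the lines, with correlations of -0.81 and -0.94, while 2 more probe sets of LOC606369 had no line effect. Among the 20 genes with the widest ranges, XIP-I (LOC542997), an inhibitor of xylanases, and WZF1 (LOC543182), a zinc finger protein, passed at limma adjusted p-values of 0.0498 and 0.0497, and each line effect ended in 12 of 16 runs that left out 1 array, after quantile normalization, with a trend and robust prior, without SB80 and without SB165.

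**Figure D1:**
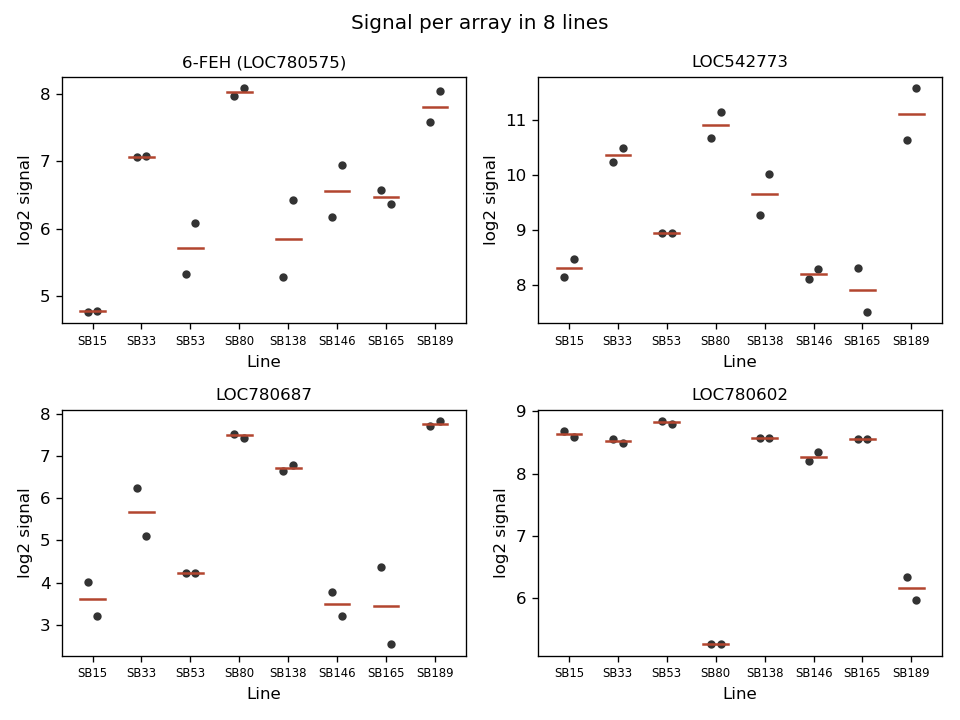
Log2 signal per array (points, 2 per line) and line mean (short lines) for 4 genes in the 8 lines, with line on the horizontal axis and log2 signal on the vertical axis, which does not start at 0. 6-FEH was lowest in SB15 at 4.77 and highest in SB80 at 8.04, and LOC780602 was lowest in SB80 at 5.27.

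In all, 2137 of 61115 probe sets (3.5%) had a line effect, of which 609 spanned a range of line means of at least 2 on the log2 scale. 79 of the 2137 were annotated, from 65 genes. 249 of the calls (11.7%) had 12 or more arrays within 0.1 of the floor, and 100 had a range of line means under 0.1. Without the dimmer probe sets, 3360 of 30557 passed, 1871 of them also called in the full set. The count rose to between 2447 and 3818 when any 1 array was left out, and 65.1% of the added calls had 12 or more arrays within 0.1 of the floor. The median intraclass correlation was 0 over 49368 probe sets that were not constant, with quartiles of -0.0406 and 0.342, and 0.189 over 30456 bright ones. A probe set with only 1 array above the floor gives exactly 0 by construction, and 6560 probe sets had a single array above the floor. The median of 0 may come from these and is no measure of a typical line effect.

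The second comparison set each line against the other 7. With all arrays, SB80 and SB165 had the most differing probe sets. SB80 had 1648, of which 37.9% were higher and 1023 lower, and SB165 had 1194, of which 72.6% or 867 were higher. The other lines had 361 (SB33) to 776 (SB189). The poly-A spike controls, RNAs added in known amounts before labelling, were also lowest in SB80 (8.82 ± 0.044, log2, SD, n = 2) and highest in SB165 (10.12 ± 0.15). With array weights SB80 had 1093. These counts rose whenever 1 array was left out, to between 1844 and 3034 in SB80 and between 1448 and 2303 in SB165, and both lines kept the first 2 places in 11 of 16 such runs. The balance of directions turned: the share that was higher in SB80 was 74.2% without its replicate 1 and 72.4% without its replicate 2, and in SB165 it ran from 44.5% without replicate 1 of SB53 to 84.3% without replicate 2 of SB165. In each of the other 6 lines the share also turned, from 24.1% to 88.1% in SB33 and from 28.1% to 77.7% in SB189, so the directions of these counts over all probe sets are not stable. Among the 30557 brightest probe sets, the share ran from 34.2% to 44.9% in SB80 and from 67.9% to 73.7% in SB165 without 1 array, and both lines kept the first 2 places in 15 of 16 runs. The 3 prime to middle difference of the sucrose synthase control, a sign of RNA quality, was highest in SB165 at 2.75 ± 0.091 and differed between lines (exact permutation p = 0.013).

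**Figure D2:**
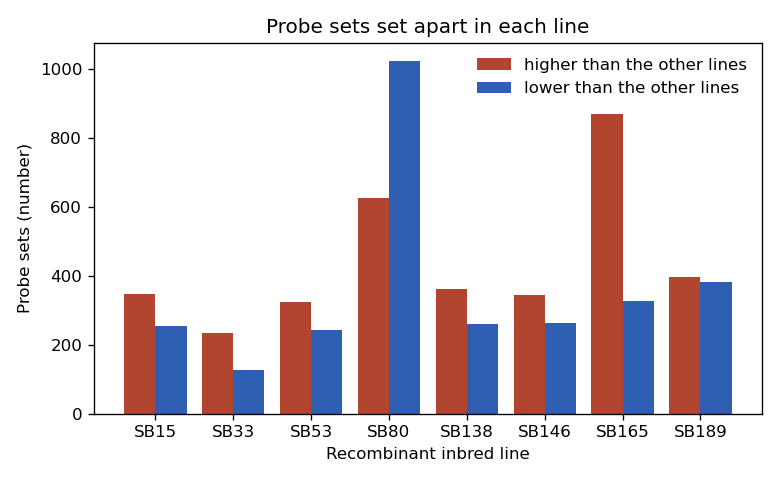
Number of probe sets higher (red) or lower (blue) in each line than in the mean of the other 7 lines at a limma adjusted p under 0.05, with line on the horizontal axis and the number of probe sets on the vertical axis. SB80 had 1023 lower probe sets and SB165 had 867 higher ones with all arrays, and the share that was higher reached 74.2% in SB80 and 44.5% in SB165 without 1 array and turned in the other 6 lines too.

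In SB80, LOC780687 was higher by 2.5 ± 0.438 (log2, SE), LOC542773 by 1.7 ± 0.294 and LOC606363 by 1.01 ± 0.19. On its brighter probe set 6-FEH was higher there by 1.0 (limma adjusted p = 0.00325), and on the one with the wider range by 1.72 (limma adjusted p = 0.0237). LOC543313 fell by 3.21 on the log2 scale, LOC780602 fell by 2.95 and LOC606345 fell by 2.03. The calls of LOC780687 and LOC606363 ended with array weights and without either array of SB80, that of LOC606363 also without SB165, and that of LOC542773 without replicate 2 of SB80. LOC606363 had no line effect over the 8 lines, and neither had its other probe set, with a mean of 7.92 and a range of 0.59 (limma adjusted p = 0.872). In SB189, LOC780687 (2.82 ± 0.438), LOC542773 (1.94 ± 0.294) and LOC100037560 (1.24 ± 0.168) were higher, and LOC780602, LOC606369 and LOC606345 were lower. The calls of the first 2 ended without replicate 2 of SB189, and that of LOC780687 also with array weights. In SB165, LOC543287 was higher by at least 6.16 (SE 0.487, limma adjusted p = 0.000685), LOC543313 by 3.81 ± 0.454 and LOC100125708 by 3.28 ± 0.508, the last not without replicate 2 of SB165 and with no line effect over the 8 lines. LOC542773, LOC542837 and 6-FEH were lower there, 6-FEH by 0.612 on its brighter probe set. This call of 6-FEH ended in 7 of 16 runs without 1 array, after quantile normalization and with a trend and robust prior. 6-FEH also lost this call with the field replicate as a block and without SB80. Its probe set with the wider range differed there by -0.07 (limma adjusted p = 1). The call of LOC542773 ended without replicate 2 of SB165 and without SB80.

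In SB15, the brighter probe set of 6-FEH fell by 0.929 on the log2 scale (SE 0.118, limma adjusted p = 0.00929). The 6-FEH probe set with the wider range differed there by -2.02 (limma adjusted p = 0.0222). LOC543100 and LOC543328 were also lower. The call of LOC543328 ended with a trend and robust prior, with the field replicate as a block, without SB80 and without SB165. It also ended without either array of SB15 and without replicate 1 of SB146. LOC543328 had no line effect over the 8 lines (limma adjusted p = 0.051). In SB33, the brighter probe set of 6-FEH was higher by 0.788 ± 0.118. This call ended without either array of SB33, with the field replicate as a block, and after quantile normalization (limma adjusted p = 0.0502). The 6-FEH probe set with the wider range did not pass there (0.61, limma adjusted p = 0.891). In SB138, GA20ox1d (LOC543325), a gibberellin 20-oxidase, was higher by 0.847 ± 0.13, and this ended without either array of SB138 and without both SB80 and SB165. Its other probe set had a range of 0.35 and no line effect (limma adjusted p = 0.872). In SB146, the beta tubulin Tubb5 (LOC543261) fell by 0.637 on the log2 scale (SE 0.0833), a call that ended without both SB80 and SB165, and LOC100049056 was higher by 1.33 ± 0.214, a call that ended without either array of SB146 and without SB165. The 3 other probe sets of Tubb5 had no line effect, with limma adjusted p-values of 0.255 to 0.872. In SB53, LOC543111 was higher by 0.739 ± 0.0902 and LOC542947 was lower, the latter not without replicate 2 of SB53 or without SB165. A second probe set of LOC543111 followed the first over line means, with a correlation of 0.98. A brighter one, at a mean of 11.99, had a line effect of its own (limma adjusted p = 0.0451) but did not follow, with a correlation of -0.0099.

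Over the 28 pairs of lines, 3738 probe sets differed in at least 1 pair. SB80 and SB165 differed most, at 1366 probe sets, of which 959 were higher in SB165. SB15 and SB53 differed least, at 450, and the median pair differed at 652. The count over all pairs ran from 3996 to 5988 when 1 array was left out, the highest without replicate 1 of SB189, and was 5671 without the dimmer probe sets.

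Only 2 of the fixed gene lists had enough members for a test. In the fructan hydrolysis list, 2 of 4 probe sets had a line effect, both of 6-FEH, against 77 of 1269 other annotated probe sets (Fisher's exact test, p = 0.021, adjusted p = 0.042), and 2 passed when adjusted over the list alone. Probe sets of 1 gene are not independent, and with 1 probe set per gene the exact p was 0.157. It was 0.203 without replicate 1 of SB15, 0.257 without replicate 2 of SB15 and 0.0503 without replicate 1 of SB189. By camera, the list was lower in SB15 (adjusted p = 0.00778) and higher in SB33 (adjusted p = 0.00778) and SB80 (adjusted p = 0.0152). With an estimated correlation the adjusted p was 0.178 in SB15, 0.178 in SB33 and 0.211 in SB80. With 1 probe set per gene the list had 2 members, under the 3 required for a set test. The adjusted p was then 0.12 in SB15, 0.003 in SB33 and 0.614 in SB80, so the calls in SB15 and SB80 ended when 6-FEH was counted once. The value in SB33 rests on 2 genes and is no test of a list. The call in SB80 also ended without the dimmer probe sets (adjusted p = 0.11). By fry, which does not compare a list with other genes, the adjusted p was 0.00621 in SB15, 0.0293 in SB33 and 0.00621 in SB80. The camera calls also ended without replicate 1 of SB80 in all 3 lines, without replicate 2 of SB80 or either array of SB33 in SB33, and without replicate 2 of SB33 in SB80.

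In the pathogenesis-related list, none of 3 probe sets had a line effect, and 1 passed when adjusted over the list alone. PR5 (LOC543292), a thaumatin-like protein, had 14.47 ± 0.21 (SD, n = 2) in SB165 and 12.51 ± 0.27 in SB80, with a limma adjusted p of 0.089 over the lines. Against the other lines PR5 was higher in SB165 by 1.24 (SE 0.21, limma adjusted p = 0.0257). In SB80 the difference of -1.0 did not pass (limma adjusted p = 0.0509). Both thionin probe sets, the other members, lay at the floor, so a result of this list is one of PR5 alone. By camera the list was higher in SB165 (adjusted p = 0.0152), and with an estimated correlation the adjusted p was 0.178. This call also ended without the dimmer probe sets (adjusted p = 0.0681) and without replicate 1 of SB165, either array of SB80 or replicate 2 of SB33. Without replicate 2 of SB165 the list passed in all 8 lines, higher in SB165 and lower in the others. By fry the list was higher in SB165 (adjusted p = 0.00214) and lower in SB80 (adjusted p = 0.0293), where camera gave 0.273. The lists for heat shock, dehydration and cold response, antioxidants, and anther and pollen had 1 or 2 members and no line effect. The members of the first 3 lists lay near the floor, with median levels of at most 2.39, where a line effect could not be seen. The profilin LOC543315, the only gene of the anther and pollen list, had means of 13.37 and 14.31 on its probe sets.

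The last comparison asked whether the field replicates differed. With limma and line as a block, 0 probe sets passed, and the lowest adjusted p was 0.13. At an unadjusted p under 0.05 there were 2605 probe sets, 4.26% of those tested, a share that counts the 11747 constant probe sets, which could not pass.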

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

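The tests on regroupings, on messenger RNA per total RNA, on probe sets without a partner or with one that did not follow, and on the spike slope of probe sets chosen by difference, and the condition on the size of the spike differences within lines, were chosen after the results had been seen. Control probe sets outside the comparisons carried signal above the 23 negative controls, which averaged 2.26. The 18S rRNA control reached 9.83 log2 units above them in its highest array and ranged from 5.11 to 12.09 over arrays. The poly-A spike controls were 1.3 log2 units higher in SB165 than in SB80, and over the 8 lines they differed more between lines than within them (exact permutation of the pairing of arrays, one-sided on the squared differences within pairs, p = 0.0075).

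The line effect of 2137 probe sets was the highest of 100 groupings of the 16 arrays into pairs, so 1 of 100 groupings, the real one, gave as many, and the highest other gave 290. Chance is excluded for this count. For the field replicates, 6 of 100 swaps of numbers within lines gave as many as the 2605 probe sets at an unadjusted p under 0.05. The other swaps had a median of 1146 and a highest count of 3600, so the real count was above the typical swap but chance is not excluded.

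With all arrays, SB80 and SB165 had the most differing probe sets and the lowest and highest spike levels, and if labelling or RNA input were the cause, these 2388 probe sets would follow the spikes within lines too. The median ratio of the within-line to the between-line slope was 0.041, which their selection for a small spread within lines lowers, and 0.15 for as many bright probe sets chosen only by their difference between the 2 lines, with values of -0.027 to 0.23 when 1 line was left out. Within lines the spikes differed by at most 0.47, too little to decide, so labelling and RNA input stay open. RNA degradation stays open, since 1 of 4 values of the 3 prime to middle difference of control genes lay outside the range of the other lines, that of sucrose synthase in SB165, a control that differed between lines (exact permutation p = 0.013). A different amount of messenger RNA per total RNA cannot be told apart from spike handling, because the spike difference of 1.3 is the only measure of either.

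Large differences, 609 probe sets with a range of at least 2, could come from sequence variants under the probes. For 157 of them another bright probe set of the same cluster but another sub-cluster exists, and the median correlation over line means was 0.869. In 1000 random draws, which paired bright probe sets regardless of cluster, it was at most 0.15. This argues against variants that touch only 1 of the paired probe sets as the whole cause. Whether partners share sequence was not checked, and a variant under both would also give a high correlation, so such variants stay open. In 19.7% the correlation was under 0.2, where variants cannot be told apart from differences in transcript level, and the probe sets of LOC780602, LOC606345 and LOC606369 also part ways, a comparison made after their values were seen. Another 452 probe sets had no such partner and cannot be told apart. Probe sets designed to match several transcripts were 22.3% of the 511 bright ones among them and 23.5% of other bright probe sets (odds ratio 0.937, 95% interval 0.752 to 1.16), and line differences in transcript level stay open, untested.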

How the results depend on the processing

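The fits without SB80, without SB165, without constant probe sets, and of bright probe sets without 1 array were chosen after the data had been seen. With a minimum log2 difference of 1, the line effect had 1212 probe sets, the pairs 1719, and the lines 250 (SB15), 167 (SB33), 235 (SB53), 575 (SB80), 241 (SB138), 249 (SB146), 490 (SB165) and 258 (SB189), fewer by construction. Without the dimmest 50% of probe sets, the line effect had 3360, the pairs 5671, SB146 961, SB165 1913 and SB189 1335. The counts of single lines among these bright probe sets also moved widely without 1 array, as in SB165 and SB189. With array weights SB80 had 1093. Without line SB80, the line effect had 1401, the pairs 2192 and SB165 795, and without both SB80 and SB165 the line effect had 981, the pairs 1399, SB15 390, SB53 344 and SB146 387. The median intraclass correlation moved from 0 to 0.1886 without dim probe sets and to 0.0063 after quantile normalization. The starting value of 0 is the one that a probe set with a lone array above the floor gives by construction. The 4 list shifts became 0 with an estimated correlation, 2 without dim probe sets and 2 with 1 probe set per gene, where each list has only 2 members. The exact p of the fructan hydrolysis share became 0.0586 without dim probe sets and 0.157 with 1 probe set per gene. For moves other than that of the minimum difference, the cause was not tested.

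Without 1 array at a time, the lone sample of a line is assumed to vary like the others, and counts rose: the line effect had 2447 to 3818, the pairs 3996 to 5988, SB15 1001 to 1882, SB33 710 to 1476, SB53 876 to 2220, SB80 1844 to 3034, SB138 986 to 2409, SB146 912 to 1934, SB165 1448 to 2303 and SB189 1117 to 3007. Of the added line effect calls, 65.1% had 12 or more arrays within 0.1 of the floor, where a lone value above the floor meets almost no residual spread. Counts over all probe sets therefore depend in part on those at the floor, but bright probe sets moved as well. Whether the share that is higher turned because of the floor was not tested, and in SB189 it turned among bright probe sets too. Among bright probe sets the line effect had 2594 to 3958. The list shifts ranged from 0 to 11 and the exact p of the fructan hydrolysis share from 0.0013 to 0.257.

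For named genes, the line effect kept its side of the threshold in 1409 of 1520 values without 1 array, with 91 lost and 20 gained, and in 1025 of 1102 others, with 63 lost and 14 gained. Differences of single lines were lost in 48 of 720 and 60 of 515. None turned direction.

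The labels number the field replicates and do not say whether a number marks a shared block. Correlations of the deviations of same-numbered replicates ran from -0.18 to 0.32 (median 0.082), and 10 of 28 pairs were over 0.1, so the numbers were not taken to pair the arrays. With the replicate block the line effect had 1986 probe sets. By limma the field replicate count was 0 in every alternative run, against 2605 at an unadjusted p under 0.05. The floor at the 25th percentile moved nothing, since that percentile is the floor, and the fructan synthesis score was not run, having no members.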

Other observations

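The gene groups and tests of this part were chosen after the results had been seen, except for the tests of neighbouring genes and of classes of lines, where the value without arrays at the floor, that without SB80 and SB165, and the comparison of class sizes were added later. Genes of photosynthesis and carbon fixation had high signals and no line effect: 0 of 8 passed, with a median level of 15, and their ranges of line means lay between 0.07 for petC and 0.22 for PsbO. PsbP was higher in SB80 by 0.1 (limma adjusted p = 0.048). The large subunit of Rubisco, rbcl, had a mean of 16.57, at the top of the scale of these arrays, which reached 16.67. Signals near the top of the scale can be compressed, so small ranges there do not show that levels were alike. Among 14 genes of grain proteins, 1 lay clearly above the floor, LOC100125692 at 11.56 on 1 of its 4 probe sets, with the others at the floor, and none had a line effect. Of 6 tubulin genes 1 passed, of 6 translation genes 1, TEF1 with a range of 0.31, a call that ended in 10 of 16 runs without 1 array and in 4 other settings, with another probe set without a line effect, of 3 gibberellin 20-oxidases 1, of 5 histones 0, and of 6 starch and sugar phosphate enzymes 0. The small subunit of ADP-glucose pyrophosphorylase, AGP-S, had a mean of 11.62 and a range of 0.38. The share with a line effect passed in no added list (two-sided Fisher's exact test, lowest adjusted p = 0.936), and lists of 3 to 14 genes are too small to exclude a difference.

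A hypothesis was that LOC542773, LOC542774 and LOC780687 share a line effect with 6-FEH. Here 6-FEH stood for a level combined over its probe sets, among them the one whose line effect ended without either array of SB15 or without SB80. Correlations with its brighter probe set alone are not given. LOC542774 and LOC780687 are neighbours in the gene order of the IWGSC CS RefSeq v2.1 annotation. Over the 8 line means, Pearson's r with 6-FEH was 0.81 for LOC542773 (exact permutation p = 0.021, adjusted p = 0.16 over 64 genes; Spearman's rho 0.6, exact p = 0.13). For LOC542774 r was 0.72 (exact p = 0.048, adjusted p = 0.23; rho 0.6, exact p = 0.13), and for LOC780687 r was 0.72 (exact p = 0.053, adjusted p = 0.23; rho 0.5, exact p = 0.22). None of the 64 genes passed. The lowest of the 6 values within 1 field replicate was 0.7, and without the 2 lines farthest from the median, SB80 and SB15, r was 0.75, 0.57 and 0.55. The differences between the replicates of a line also went together, with r of 0.71 (exact p = 0.041, adjusted p = 0.26; rho 0.6, exact p = 0.13), 0.87 (exact p = 0.0031, adjusted p = 0.05; rho 0.76, exact p = 0.037) and 0.85 (exact p = 0.0076, adjusted p = 0.097; rho 0.88, exact p = 0.0072). No gene passed there either, and without the 2 farthest lines these r were 0.17, 0.56 and 0.63. Variation between plots that these genes share may therefore add to the correlation of line means, and a shared line effect is not decided.

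If single loci segregating between the parents set the large differences, line means may fall into 2 classes. The best split into 2 classes took a median of 89.3% of the variation between line means over the 609 probe sets. It took 87.5% over the 503 with no array at the common floor, and at most 77.2% in 1000 draws from normal values. Over the 6 lines other than SB80 and SB165 the best split took 94.1% in 440 probe sets, against at most 81.2%. Above the common floor, arrays of different lines still had equal values for a median of 11.2% of probe sets. Lines with equal values fall into the same class by construction, and draws from normal values have no such ties. How far ties raised these shares was not tested, so the draws do not decide whether line means form 2 classes. Class sizes did not follow a single locus, however: 19.4% of the splits set 1 line apart, where segregation at equal odds gives 6.3%, and most of these were SB165 high (59) or SB80 low (31), the lines at the ends of the spike levels. Probe sets share loci and are not independent, so a single locus per probe set is left open. Annotated genes within 5 places of each other did not follow each other more than random pairs: the median correlation was 0.051 over 10 pairs, and 1000 random draws had a median of 0.034 and a 95th percentile of 0.32, too few pairs to decide whether linked segments could be seen.

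Among unnamed probe sets the widest ranges of line means were 10.09 and 9.02. The latter probe set was low in SB53 (2.6) and SB138 (2.83) and lay between 9.55 and 11.62 in the other lines.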
